A study of Arabidopsis thaliana with 4 samples.

How the data were processed

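Genomic DNA from MM2d, a suspension-cultured cell line of Arabidopsis thaliana, was compared between DNA that had taken up the thymidine analogue bromodeoxyuridine (BrdU), which marks newly replicated strands, and DNA without the label. There were 4 libraries, with 2 BrdU libraries and 2 unlabelled libraries numbered 1 and 2 in the labels. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries were sequenced on a Genome Analyzer II, per the labels' protocols.

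The deposited files hold the positions of aligned reads, a row per read and nothing counted or normalised. The aligner, the mismatch and uniqueness rules and the genome build are not given in the sources used here, apart from name tags on the replicate 2 files that read as unique placements of 50-base reads with up to 3 mismatches. The replicate 1 files give a start and an end for each read on the 5 nuclear chromosomes. The replicate 2 files give 1 position per read, counted from 0, and also cover the chloroplast and mitochondrial genomes. Cross-correlation of the replicates on each chromosome peaked at a shift of -1 bp for forward reads and 48 bp for reverse reads, on all 5 chromosomes. Positions were therefore brought to the 5' end of each read, counted from 1, and both replicates were treated as lying on the same build. The last read positions were 30432307, 19705151, 23470769, 18585042 and 26992728 bp on chromosomes 1 to 5. Neither a genome sequence nor an annotation of that build was used here, so the comparisons by gene, gene list, gene end, annotation class and GC content were not run, and regions are described by position alone.

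Reads were counted at their 5' ends in windows of 5 kb, and windows with at least 40 reads over the 4 libraries were tested with limma 3.58.1 in R 4.3.3, using voom with nuclear read totals, moderated two-sided tests and Benjamini-Hochberg adjustment at 0.05, without a block. The tests ask whether the ratio on nuclear totals differs from 0 on the log2 scale, while fold changes are printed relative to the median window, which lay at -0.69 in that fit. On simulated reads for 23155 windows at the real depths, with noise of 0.2 (SD, log2), the fit called 100 of 100 windows raised 4-fold and 100 of 100 raised 16-fold. With noise of 0.912 (SD, log2), it called 4 of 100 windows raised 4-fold, 65 of 100 raised 16-fold and 1 of 22955 unchanged windows. The size 0.912 was the median residual SD of the weighted fit without 3 to 4 Mb of chromosome 2 (0.823 with that stretch). The simulation also leaves that stretch out. That SD is scaled by the voom weights and is not in log2 units, and the simulated noise was alike in all windows. Neither simulation therefore gives the power or the rate of false calls on these data. The named windows are the 5 with the highest and the 5 with the lowest moderated statistic, and the named domains are the 5 widest, a rule fixed before the data were examined together with the tests, groups and a first set of alternative settings.

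Ratios per replicate were log2 of BrdU over unlabelled reads per nuclear read, with 0.5 added to each count. Called windows were merged into domains across gaps of at most 1 window. Correlations across windows were set against 1000 circular shifts of the windows along each chromosome, whose smallest p is 0.001. Pericentromeres were taken as 2 Mb to each side of a centre on each chromosome. The planned centre needed an annotation, so it was replaced, after the data were seen, by the 1 Mb stretch with the most 1 kb windows in which unlabelled DNA held over 4 reads per distinct position. Those centres lay at 15.1, 3.4, 13.9, 3.5 and 11.6 Mb on chromosomes 1 to 5, and the centre of chromosome 1 rested on only 6 such windows. Shares of reads carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

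Narrow peaks were added after the data were seen. A 1 kb window was a peak in a library if it held at least 10 distinct positions (position and strand) and at least 5 times the running median over 101 windows, with a floor of 2, outside 3 to 4 Mb of chromosome 2. On simulated positions over 118189 windows the rule found 95 of 100 windows raised 8-fold in both BrdU libraries, 99 of 100 raised 16-fold and 0 of 117989 unchanged windows. The simulated counts were independent Poisson draws around the running medians, while the real positions varied more between windows than counting error gives. The 0 was practically fixed by that setting and gives no false positive rate for these data. Local ratios divide each count by its running median. Neighbouring peak windows were joined across gaps of at most 1 kb. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

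The libraries differed in depth and in repeated reads. BrdU replicate 1 held 8162218 reads, of which 47.16% lay at distinct positions, and unlabelled replicate 1 held 11926392 reads, with 82.16% distinct. BrdU replicate 2 held 2474575 reads, 1655602 of them nuclear with 41.22% distinct. Unlabelled replicate 2 held 19257038 reads, 13143687 of them nuclear with 78.05% distinct. Alternatives covered the replicate block, scaling by median of ratios, repeated reads, filters, window size, fold threshold, pericentromere extent and each library left out; those added after the data were seen leave out 3 to 4 Mb of chromosome 2, test against the median window, combine choices or change the peak rule.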

Results

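The study set newly replicated DNA, marked with BrdU, against unlabelled DNA of the same plant cell line, MM2d, with the stated purpose of locating where replication starts. Each group had 2 libraries. Nuclear reads numbered 8162218 and 1655602 in BrdU replicates 1 and 2, and 11926392 and 13143687 in unlabelled replicates 1 and 2. The median 5 kb window held 123 distinct read positions in BrdU replicate 1 and 25 in BrdU replicate 2, against 364 and 289 in unlabelled replicates 1 and 2, so windows were measured least precisely in BrdU replicate 2.

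Short stretches with an excess of BrdU-labelled DNA recurred in both replicates, by a rule set after the data were seen. At a resolution of 1 kb, 191 windows rose at least 5-fold over their surroundings in both BrdU libraries and in neither unlabelled library. Circular shifts gave 1.95 such windows on average and at most 8 in 1000 shifts (permutation p = 0.001, the smallest they can give). Shared peaks as such were not particular to BrdU: with peaks of the unlabelled libraries kept in, all 6 pairs of libraries shared more peak windows than any shift, with 616 for the BrdU libraries, 43.3 times the mean of the shifts, and 604 for BrdU and unlabelled replicate 1, 57.8 times. The 191 windows formed 170 regions, of which 152 were a single window and the widest spanned 5 kb, with a median spacing of 479 kb. Some regions were piles of repeated reads. The widest, at 3951001 to 3956000 bp of chromosome 4, held 19519 reads at 1374 positions in BrdU replicate 1. In unlabelled replicate 1 it held 36981 reads at 1881 positions. The region at 14209001 to 14211000 bp of chromosome 3 held 31187 reads at 399 positions in BrdU replicate 1. Across the regions the median local ratio of BrdU to unlabelled positions was 8.62-fold in replicate 1 and 4.86-fold in replicate 2. The rule asks for at least 5-fold in both BrdU libraries and for less in both unlabelled ones. This fixes the direction of these ratios and makes their sizes upper estimates. Unlabelled DNA was not always flat in the regions, with medians of 0.91 and 2.41 times the surroundings in unlabelled replicates 1 and 2.

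The region at 28522001 to 28523000 bp of chromosome 1 held 330 distinct positions in BrdU replicate 1 and 300 in BrdU replicate 2, which were 14.3 and 60 times the local median, against 54 and 177 in unlabelled replicates 1 and 2, or 0.71 and 3.4 times. At 1478001 to 1479000 bp of the same chromosome the counts were 350 and 245 in the BrdU libraries and 13 and 73 in the unlabelled ones, with local log2 ratios of 6.13 and 5.59. On chromosome 2, 8557001 to 8559000 bp had local log2 ratios of 3.97 in replicate 1 and 3.50 in replicate 2. On chromosome 3, 19477001 to 19478000 bp had ratios of 4.08 and 3.50, and on chromosome 4, 149001 to 150000 bp had ratios of 4.27 and 3.28. The region at 11576001 to 11577000 bp of chromosome 5, in the pericentromere, rested on 44 and 42 positions in the BrdU libraries against 4 and 28 in the unlabelled ones. These regions were chosen after their values were seen, from the 10 with the highest fold in the weaker BrdU library. In replicate 2 the local log2 ratio was 2.90 in the chromosome 5 region. In those of the 10 not named here it ranged from 1.43 to 3.01.

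**Figure D1:**
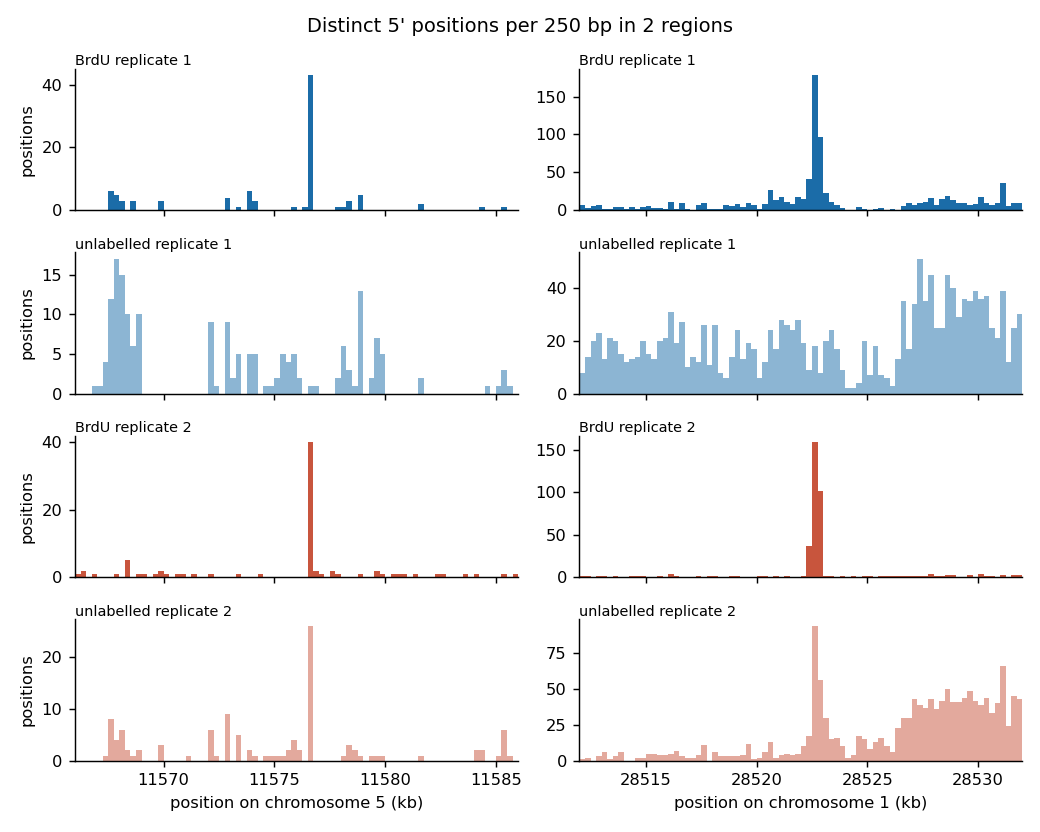
Bars give distinct 5' read positions per 250 bp (y axis) along 20 kb (x axis, kb) of chromosome 5, left, and chromosome 1, right, with a row for each of the 4 libraries and its own y scale. Both BrdU libraries peak in the same 1 kb at 11576001 and at 28522001 bp, where unlabelled replicate 1 shows no peak and unlabelled replicate 2 shows a smaller peak, with 28 and 177 positions.

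The 170 regions were spread over all 5 chromosomes, with 37, 21, 43, 34 and 35 on chromosomes 1 to 5, or 1.22, 1.07, 1.83, 1.83 and 1.30 per Mb. Of the 191 windows, 34 lay in the pericentromeres and 157 in the arms. Circular shifts put 31.1 in the pericentromeres on average, within a range of 14 to 50, so no preference for arms or pericentromeres was found (permutation p = 0.735, two-sided).

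Averaged over peaks chosen in replicate 1 alone, the signal of BrdU replicate 2 was highest at the same place, though 432 of 1522 such windows were peaks in BrdU replicate 2 themselves. Over the 1073 regions that peaked in BrdU replicate 1 and not in unlabelled replicate 1, the mean signal at the centre was 6.01 times the flanks in BrdU replicate 1 and 6.52 times in BrdU replicate 2, against 1.89 and 2.43 times in unlabelled replicates 1 and 2. The choice itself sets the contrast within replicate 1, so only the replicate 2 values are free of it. Midway between flanks and summit the mean peak was 600 bp wide in BrdU replicate 1 and 400 bp wide in BrdU replicate 2. Forward reads made up 49.9% and 50.1% of the positions in these regions in BrdU replicates 1 and 2.

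**Figure D2:**
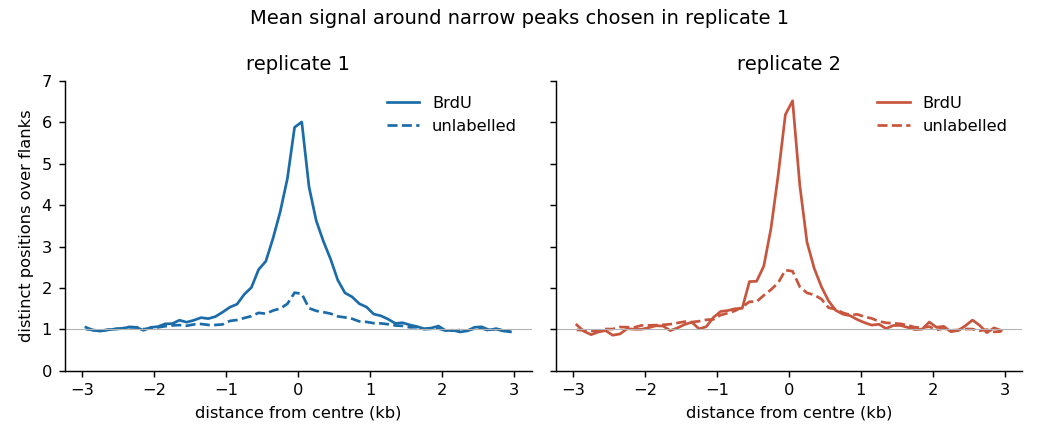
Lines give the mean number of distinct positions per 100 bp, divided by the mean of the outermost flanks (y axis), against distance from the centre in kb (x axis), over 1073 regions chosen in replicate 1 only, for BrdU (solid) and unlabelled DNA (dashed). The BrdU libraries reach 6.01 and 6.52 at the centre and the unlabelled libraries 1.89 and 2.43. The contrast within replicate 1 is set by the choice of regions.

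The check across replicates was uneven. Of 335 windows that peaked in BrdU replicate 2 and not in unlabelled replicate 2, 327 had more BrdU than unlabelled signal in replicate 1, or 97.6% (95% exact interval 95.4 to 99.0), with a median of 5.14-fold. In the other direction, 490 of 1500 windows that peaked in BrdU replicate 1 and not in unlabelled replicate 1 had more BrdU than unlabelled signal in replicate 2. That was 32.7% (30.3 to 35.1), against 48.2% of all windows, with a median of 0.62-fold. The mean profile around the peaks of replicate 1 therefore does not describe the typical such window in replicate 2. Among those that did not peak in unlabelled replicate 2 either, a choice that itself favours BrdU in replicate 2, the share was 432 of 728, or 59.3% (55.7 to 62.9). Unlabelled replicate 2 also had far more peaks than any other library, 5839 against 765 in unlabelled replicate 1, 2126 in BrdU replicate 1 and 884 in BrdU replicate 2. Of 432 windows that peaked in both BrdU libraries and not in unlabelled replicate 1, 241 peaked in unlabelled replicate 2 as well.

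In windows of 5 kb, 18 of 23349 were higher in BrdU DNA and 0 were lower (limma, adjusted p under 0.05, against a ratio of 0 on nuclear totals), and 116 and 476 passed an unadjusted 0.05. Tested against the median window, at -0.69 on that scale, 65 were higher and 0 lower. All 18 lay above the median ratio in both replicates, though 2 of them held no read in either library of replicate 2. Of these, 3 lay at 3 to 4 Mb of chromosome 2, and 7 of the other 15 held at least 5 reads per distinct position in a BrdU library. The remaining 8 lay between 3.27 and 4.13 above the median on the log2 scale, and each of them held a narrow peak found in both BrdU libraries and not in unlabelled replicate 1. By the rule of the 191 windows, which also bars a peak in unlabelled replicate 2, 6 of the 8 held one. Calls and peaks come from the same reads, so this overlap is no independent check. The calls did not survive leaving out 3 to 4 Mb of chromosome 2, keeping 1 read per position or scaling by median of ratios. Each of these settings gave 0 higher and 0 lower in limma. At an unadjusted 0.05 they gave 286, 253 and 335 higher and 2, 8 and 0 lower. Chance alone would put a share of about 0.05 of the windows under that limit, higher and lower counted jointly. The main fit and these settings each stayed below that share, so their unadjusted counts show no excess over chance. Without BrdU replicate 1 or BrdU replicate 2 the fit gave 0 higher and 0 lower, with 80 and 46 higher at an unadjusted 0.05, without unlabelled replicate 1 it gave 116 higher and 1882 lower, and without unlabelled replicate 2 it gave 112 and 840. The median window lay at -0.46 and -0.94 in these last fits, and against it they gave 130 higher and 355 lower, and 450 and 2.

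The 5 windows with the highest moderated statistic were on chromosomes 2 and 5. The window at 8555001 to 8560000 bp of chromosome 2 lay 4.13 ± 0.63 (log2, SE, n = 2 and 2) above the median (limma, adjusted p = 0.000226 for the test against a ratio of 0), with 596 and 530 reads in the BrdU libraries and 148 and 269 in the unlabelled ones. The window at 7195001 to 7200000 bp lay 4.47 ± 0.66 above it (adjusted p = 0.000108), on 9.06 and 6.14 reads per distinct position in the BrdU libraries. The window at 8555001 bp stood at 3.83 ± 0.50 without 3 to 4 Mb of chromosome 2, 3.48 ± 0.57 with 1 read per position and 3.83 ± 0.65 with median of ratios, and that at 7195001 bp at 4.06 ± 0.51, 1.80 ± 0.64 and 4.18 ± 0.75. The prior degrees of freedom that limma estimated fell from infinite to 2.91, 2.42 and 4.47 under these settings, in which neither window passed. At 12610001 to 12615000 bp of chromosome 5 the value was 4.32 ± 0.64, resting on 2856 reads at 39 positions in BrdU replicate 2, and 1.22 ± 0.63 with 1 read per position. The other windows, at 3285001 and 3375001 bp of chromosome 2, lay 8.34 ± 1.33 and 4.77 ± 0.72 above the median, and held 0 and 45 reads in BrdU replicate 2 and 0 and 3 in unlabelled replicate 2. The first of these fits rests on replicate 1 alone, where the measured ratio was 3.49 above the median. With limma trend that window was at 3.08 ± 1.29 and did not pass. The second had measured ratios of 2.71 and 6.41. Its value depended on single libraries, with 1.04 without unlabelled replicate 2 and 11.2 without unlabelled replicate 1. The 5 windows with the lowest statistic, at 5585001, 5580001 and 4045001 bp of chromosome 4, 3970001 bp of chromosome 2 and 23170001 bp of chromosome 3, lay between -1.41 and -1.29 and did not pass (adjusted p = 0.753 for each), though all 5 passed without unlabelled replicate 1, at -2.32 to -1.85 (adjusted p from 0.000113 to 0.00222), and 3 without unlabelled replicate 2, where the 5 lay at -0.67 to -0.20. Tested against the median window, 4 passed in the first of these fits and 0 in the second.

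The 18 windows formed 17 domains. The widest, 10 kb at 3370001 to 3380000 bp of chromosome 2, joined 2 called windows, and the other 16 were single windows of 5 kb, so the widths give no further order. Their median spacing was 3.05 Mb. Circular shifts move the calls together and leave the number of domains unchanged, so they provide no test here.

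Over broad stretches the replicates ran in opposite directions. The Spearman correlation of their log2 ratios across 23349 windows of 5 kb was -0.42 and the Pearson correlation -0.33, where 95% of circular shifts gave Spearman values between -0.03 and 0.04 (permutation p = 0.001 for each, the smallest they can give, for windows, which are not independent replicates). At 100 kb the Spearman correlation was -0.46. The top 5% of windows, 1167 in each replicate, shared 57, where independent lists would share 58.3. In windows of 1 kb, 10 kb and 100 kb they shared 374, 39 and 6, against 267, 29.5 and 3.02, so the highest windows overlapped somewhat more at other sizes. With 1 read per position at 5 kb they shared 71 against 58.2, but 42 against 57.7 when 3 to 4 Mb of chromosome 2 was also left out. These overlaps were not tested. In replicate 1 the last 1 Mb lay above the median window at 9 of the 10 chromosome ends, up to 0.30 on the log2 scale at the bottom of chromosome 1. In replicate 2 all 10 ends lay below it, down to -0.85 at the same end.

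**Figure D3:**
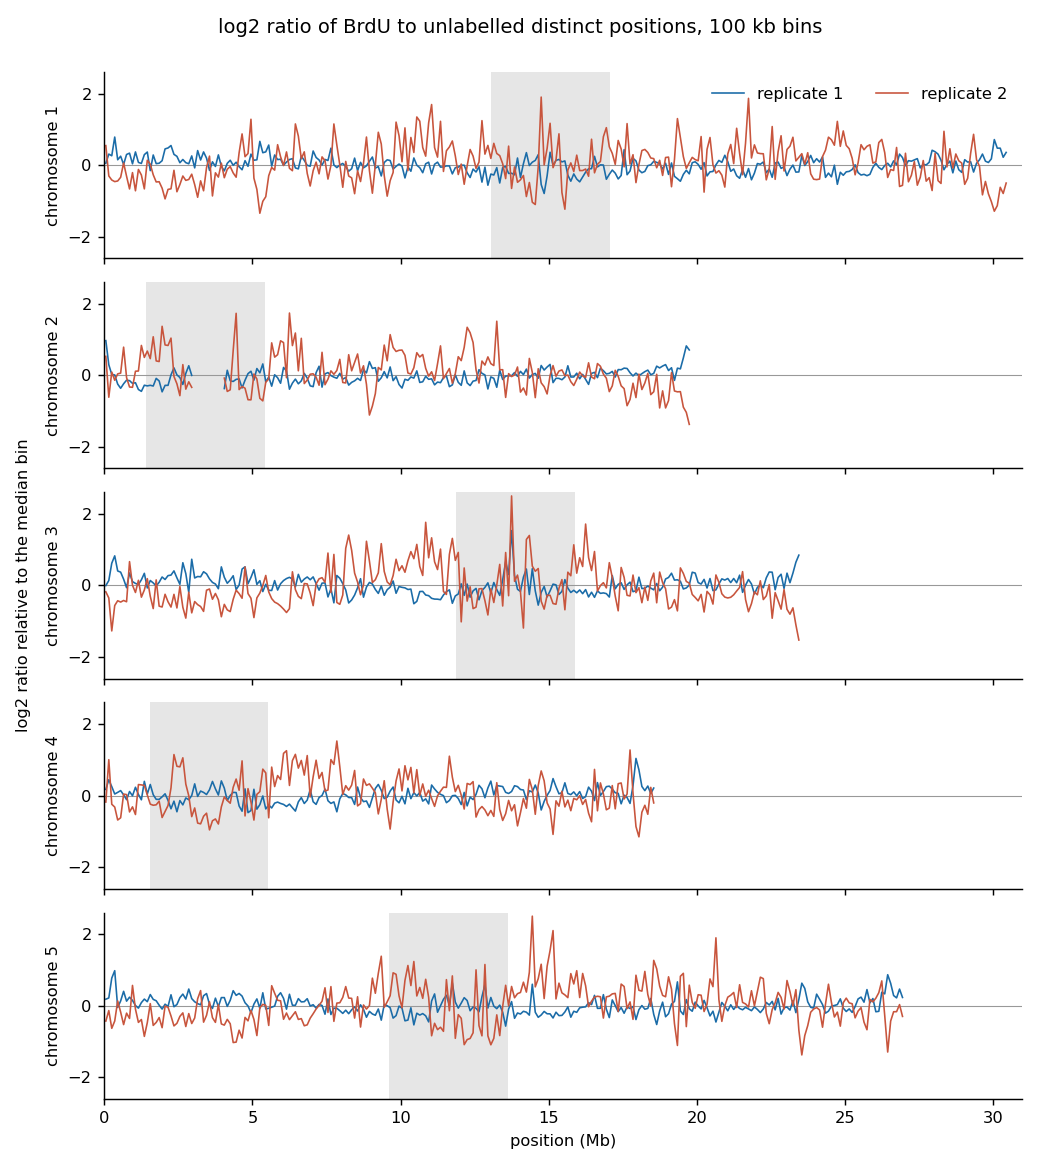
Lines give the log2 ratio of BrdU to unlabelled distinct positions in bins of 100 kb relative to the median bin (y axis, limited to 2.5 in size) along each chromosome in Mb (x axis), for replicate 1 (blue) and replicate 2 (red), with pericentromeres shaded and 3 to 4 Mb of chromosome 2 left out. The lines mirror each other, with a Spearman correlation of -0.58 across 1184 bins.

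The difference between chromosome arms and pericentromeres had no settled direction. Arms minus pericentromere was -1.85 in replicate 1 and -0.22 in replicate 2 on the log2 scale, or -1.04 ± 1.15 (SD, n = 2). With 2 libraries in each group an exact permutation of the labels cannot give a two-sided p below 0.333. Without 3 to 4 Mb of chromosome 2 the difference was -0.32 ± 0.05, and on distinct positions without that stretch it was 0.07 ± 0.01, each larger than the spread of the replicates but of opposite sign. By chromosome, on those positions, replicate 1 had higher medians in the arms on 5 of 5 chromosomes and replicate 2 on 1 of 5 (chromosome 4).

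A stretch of chromosome 2 took a large part of the reads of replicate 1. The megabase from 3 to 4 Mb held 48.8% of nuclear reads in BrdU replicate 1 and 13.4% in unlabelled replicate 1, against 3.13% and 4.68% in BrdU and unlabelled replicate 2. The excess came from 47 windows between 3245001 and 3505000 bp, where the median window held 598 and 80.2 times the reads of the median genome window in BrdU and unlabelled replicate 1, and 8.9 and 17.6 times in BrdU and unlabelled replicate 2. By distinct positions these values were 74.4, 21.1, 5.68 and 1.10, of which those of replicate 1 are lower bounds, since a window has a limited number of positions and 9145 and 7691 were taken.

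Organelle reads were listed for replicate 2 only. The chloroplast genome took 6.97% of reads in the BrdU library (95% exact interval 6.93 to 7) and 3.51% in the unlabelled library (3.50 to 3.52). The mitochondrial genome took 26.1% (26.1 to 26.2) and 28.2% (28.2 to 28.3). With 1 read per position the shares were 7.56% and 1.21% for the chloroplast and 13.9% and 1.88% for the mitochondrion, but this measure saturates on small genomes (5437483 unlabelled mitochondrial reads lay at 198524 positions), so it decides no direction. These are single libraries, so the differences have no replicate check.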

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

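The share of reads on the chloroplast genome, outside the nuclear comparisons, was 6.97% in BrdU replicate 2, above the 3.51% of the unlabelled library of the same number. Relative to nuclear reads the chloroplast was 1.02 higher on the log2 scale in the BrdU library, while the mitochondrion differed by -0.08. On distinct positions these values were 2.95 and 3.19, but positions saturate on genomes this small, so they decide nothing about the contrast. Replicate 1 lists no organelle reads, so no biological or technical account of the difference was tested.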

How the results depend on the processing

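Alternatives that leave out 3 to 4 Mb of chromosome 2, test against the median window, combine choices, cross the pairing or change the narrow peak rule were chosen after seeing the data. The 18 windows of 5 kb higher in BrdU DNA (0 lower) became 64 in 2 kb windows, 103 in 1 kb windows and 3 in 10 kb windows. They became 0 with 1 read per position, with median of ratios size factors, without 3 to 4 Mb of chromosome 2, and on distinct positions with median of ratios outside that stretch, in 5 kb and in 1 kb windows. With single libraries left out, where a lone sample is assumed to vary like the other group, they ranged from 0 to 116 higher and from 0 to 1882 lower. Same-numbered libraries did not deviate together (Pearson -0.05, Spearman -0.12 across 23349 windows), so the block stayed out of the main fit. However, both replicate 1 libraries carry the chromosome 2 excess, and the files of the replicates differ in form and in the genomes listed. How the files were made thus differed by replicate number, and a batch shared by same-numbered libraries is not excluded. A replicate block gave 164 higher and 1919 lower windows and 155 domains in place of 17, a crossed pairing gave 8 higher and 0 lower, and the block on distinct positions with median of ratios outside the stretch gave 117 higher and 0 lower. Against the median window the main fit gave 65 higher, the block 459 higher and 6 lower, and the fits without unlabelled replicate 1 or 2 gave 130 and 450 higher and 355 and 2 lower. The window at 3285001 bp of chromosome 2 turned to -3.36 without BrdU replicate 1, at the low end of a range up to 13.2 with single libraries left out; the other 189 of 190 alternatives of the 10 named windows kept their direction, with 33 calls lost and 15 gained. Among the alternatives of the named windows, the fold threshold and the tests against the median window could change no direction, since they repeat the values of another fit. The 10 windows were also chosen for extreme statistics in the same reads, so their kept directions are a weak check. Arms minus pericentromere turned to 0.072 on distinct positions outside the stretch and to 0.093 as a median window ratio. On distinct positions the chloroplast took 7.56% (BrdU) and 1.21% (unlabelled) and the mitochondrion 13.9% and 1.88%. The 191 shared narrow peak windows became 502 at 3-fold, 63 at 10-fold, 448 of 500 bp and 65 of 2 kb. The cause was not tested, except that window size changes the number of windows and that prior degrees of freedom fell from infinite to between 2.42 and 7.73 in 4 of the 5 single settings with 0 calls (not without BrdU replicate 2). The correlation of the replicates stayed negative in all 8 settings, from -0.46 to -0.24 (-0.58 in 100 kb bins of distinct positions outside the stretch). Depth limits BrdU replicate 2 most. GC corrections, all alternatives by gene, gene list, gene end, annotation class and GC content, and organelle shares of replicate 1 were not run.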

Other observations

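All tests of explanations below were chosen after the results were seen. The 2 windows that took the largest mean share of reads outside 3 to 4 Mb of chromosome 2 were both richer in BrdU DNA in each replicate. The window at 14210001 to 14215000 bp of chromosome 3 took 2.42% and 9.80% of these reads in BrdU replicates 1 and 2, against 0.0815% and 0.895% in the unlabelled libraries, a ratio of 29.7-fold in replicate 1 and 10.9-fold in replicate 2. The window at 5001 to 10000 bp of chromosome 2, a chromosome whose top carries ribosomal RNA gene arrays in textbook maps, was 30.7-fold and 15.2-fold higher. Reads of the first over reads of the second were 2.99 and 2.68 in the BrdU libraries and 3.09 and 3.73 in the unlabelled ones. Both windows held at most 1132 distinct positions in any library, so these are ratios of heavily repeated reads, and neither window passed the adjusted threshold.

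Broad ratios of opposite sign in the 2 replicates go with the unlabelled library of replicate 2. Distinct positions per 5 kb in that library had quartiles of 119 and 578, a ratio of 4.86, against 1.89 in unlabelled replicate 1, 2.45 in BrdU replicate 1 and 2 in BrdU replicate 2. BrdU replicate 2 alone correlated positively with the replicate 1 ratio (Spearman 0.47 at 5 kb), and unlabelled replicate 2 alone did so more strongly (0.51). Given unlabelled replicate 2, BrdU replicate 2 kept a partial rank correlation of 0.10 at 5 kb and -0.02 at 100 kb. Unlabelled replicate 2 given BrdU replicate 2 kept 0.25 and 0.32. Most of the 0.47 was thus shared with unlabelled replicate 2. The sign turned only with unlabelled replicate 2 subtracted, so an uneven unlabelled library may be part of the source. An exchange of the BrdU and unlabelled libraries of replicate 2 is argued against, since 97.6% of windows that peaked in BrdU replicate 2 and not in unlabelled replicate 2 had more BrdU than unlabelled signal in replicate 1, although 82.1% of windows that peaked in unlabelled replicate 2 and not in BrdU replicate 2 did too, by a median of 1.48-fold. What made that library uneven, and why its unevenness follows the replicate 1 ratio, was not tested.

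The excess of replicate 1 reads at 3 to 4 Mb of chromosome 2 lies where textbook maps place a nuclear copy of mitochondrial DNA. Mitochondrial reads placed on that copy could account for it, but the tables do not decide. Replicate 2, which lists mitochondrial reads apart, stood at 1.10 (unlabelled) and 5.68 (BrdU) times its genome medians there by distinct positions, and at 17.6 and 8.9 times by reads, against 80.2 and 598 times by reads in replicate 1. More copies of the stretch in the replicate 1 culture cannot be told apart from this. Of 137 windows there at or above the median in unlabelled replicate 1, only 3 were nearly empty in unlabelled replicate 2. Elsewhere 15 of 11559 such windows were (0.13%), so nearly empty windows were more frequent in the stretch, but 3 are too few to decide. No biological explanation was tested.

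Narrow peaks were shared by both BrdU libraries and partly present in unlabelled replicate 2. Repeated sequence collapsed in the reference would raise both replicate 1 libraries alike if both held it in equal shares. Of all windows that peaked in BrdU replicate 2, 92.3% had more BrdU than unlabelled signal in replicate 1. The median was 2.59-fold. That share is not particular to BrdU peaks, since it was 82.1% in windows that peaked in unlabelled replicate 2 and not in BrdU replicate 2, with a median of 1.48-fold. Equal shares cannot be assumed either. The 2 windows of heavily repeated reads named above were 29.7-fold and 30.7-fold richer in BrdU in replicate 1. The 92.3% therefore cannot decide about repeated sequence. Carry-over of the same molecules from the BrdU to the unlabelled library of replicate 2 was tested only in the 170 regions. The windows that formed them were chosen for no peak in unlabelled replicate 2. There the read starts of these 2 libraries coincided 1.45 times as often as at offsets of 5 to 30 bp. This was within the 1.34 to 1.75 of the other 5 pairs of libraries, which argues against carry-over in those regions only. Windows that peaked in both BrdU libraries and in unlabelled replicate 2 were not chosen, so the test cannot decide about their peaks. A sequence or fragmentation bias that unlabelled DNA also carries cannot be told apart from uptake of the label near sites where replication starts, the study's question, because the unlabelled libraries differ: in the 432 windows that peaked in both BrdU libraries and not in unlabelled replicate 1, unlabelled replicate 2 stood at a median of 6.23 times its surroundings and unlabelled replicate 1 at 1.55 times. The choice of the 432 windows itself holds unlabelled replicate 1 low. Over all 616 windows that peaked in both BrdU libraries, unlabelled replicates 1 and 2 stood at 2.65 and 8.52 times. BrdU replicates 1 and 2 stood at 8.24 and 7.5 times there, so unlabelled replicate 2 was raised about as much as the BrdU libraries.

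Stretches without a read in any of the 4 libraries were longest at 14406633 to 14482040 bp of chromosome 5, 75.4 kb, and at 14748080 to 14821500 bp of chromosome 1, 73.4 kb.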
